A study of Homo sapiens with 6 samples.

How the data were processed

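Expression was measured in breast cancer cells, MDA-MB-231 per the labels, without CTI-2 (3 control libraries) or after 24 h with CTI-2 (3 libraries). Per the labels' protocols, RNA was harvested in Trizol and cDNA libraries were made with the Oxford Nanopore cDNA-PCR kit. Per the labels the control libraries had no agent, and whether they received a vehicle is not given in the sources used here. The submitters' processing notes name minimap2, an aligner for long reads. Its version, the genome build, the annotation, the read counter, any use of strand and any filter are not given in the sources used here. The authors deposited whole-number read counts per gene for each library, and a table of CPM. The deposited CPM equalled each count divided by its library's total and scaled by 1000000, to within 1e-09 for all 16362 genes, so both tables hold the same information. cDNA reads were amplified and carry no molecular identifiers, so intervals and floors cover counting error only.

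The table held 16362 genes, 14408 of them under Ensembl identifiers and 1954 under identifiers of the authors' own. Those that the authors typed as new genes took 2.05 to 3.05% of counts. All 14408 Ensembl identifiers are in GENCODE 29, and the deposited gene length equals the end minus the start of the GENCODE 29 span for 80.6% of them. Coordinates are therefore given from GENCODE 29 on GRCh38, 1-based, only for genes whose span is equal, and the authors' own build is not given in the sources used here. Genes that share sequence with paralogs or pseudogenes, and genes that overlap on either strand, are uncertain because the counting could split or drop their reads. Beside those noted in the results, KLRC3, KRT8, KRT18, CHAF1A, ANKRD37, TUBA1A, MT-CO3, MT-ATP8 and ATP5PO overlap another counted gene.

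Samples were grouped by the agent in the labels. Counts were filtered with edgeR's filterByExpr at its defaults (9848 genes kept), scaled by TMM and tested with edgeR 4.0.16's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, CTI-2 minus control. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Log2 fold changes come from this fit, and their SE was derived from the fold change and the test statistic. The common biological coefficient of variation was 0.100. CPM are the deposited values, given as mean ± SD of 3 libraries. Before the data were examined 29 gene lists were fixed, and the 26 with at least 5 tested members were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 26 lists. Shares of counts were compared by a two-sided exact permutation test, which for 3 against 3 libraries cannot give a p under 0.1. Intervals of shares are 95% exact binomial (Clopper-Pearson) intervals.

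The rule for the genes named was also fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among called genes with a symbol, a mean of at least 10 counts in the higher group and no overlap between groups, up to 3 called members of each list by adjusted p, up to 2 members of highest CPM of a list without calls, and 14 genes of interest regardless of outcome, of which 13 were in the table. Genes named beyond this rule (ARAF, IER3, EPHA2, DUSP4, LSS, PDIA4, CALR, ASNS, TRIB3, DDIT3, MT-ND5, MT-ND6, COL5A1, UQCRFS1, COX5A, COX6C, KRT10, CNBD2, AC007240.1 and AL713999.1) were chosen after their values were seen. Some genes that the rule took are not reported here. Some list members carry older symbols in the table and were matched by identifier.

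Alternatives fixed in advance were DESeq2's size factors, library totals, no low-count filter, a filter of 20 counts in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(CPM + 1) and log2(CPM + 0.5), the replicate number as a block, leaving out each library, a fold change over 1.5 (glmTreat), an adjusted p of 0.01, camera with an estimated correlation, and fry. Chosen after seeing the data were the restriction to genes with an annotated transcript, removal of each library's lowess trend (span 0.3) with transcript length or GC content, and thinning of all libraries to the smallest total. Transcript length and GC content came from GENCODE 29 transcripts and were available for 93.6% of tested genes.

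The fit was tested on simulated counts drawn from the real libraries' means and totals. Of the genes changed in the simulated CTI-2 minus control comparison (9654 genes in the fit), it recovered 43.9% at 1.5-fold, 77.3% at 2-fold and 100% at 4-fold, and 4 of 147 calls were false. A simulated list of 20 genes shifted by -0.4 on the log2 scale was called, and 1 of 100 random lists was. The simulated genes were drawn independently, so this rate does not cover lists whose members vary together. No pair of same-group libraries agreed within sampling noise (chi-square per degree of freedom 1.78 to 6.92), so none was treated as 1 library deposited again; this does not show that they came from separate cultures. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.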

Results

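Gene expression was measured in cells that the labels name as MDA-MB-231, a human triple-negative breast cancer line commonly described as mesenchymal, cultured for 24 h with or without CTI-2. CTI-2 is known here only by its code name, and its dose is not given in the sources used here. There were 3 control libraries and 3 CTI-2 libraries, each made from total RNA with a cDNA-PCR kit and read on the Oxford Nanopore platform, which reads whole cDNA molecules. Total counts were 2596184, 3929532 and 2349758 in controls 1 to 3 and 3153469, 2966992 and 2208261 in CTI-2 libraries 1 to 3, spread over 13908 to 14716 genes with a count. At these depths 3 counts in a library correspond to 0.763 to 1.36 CPM, the counts scaled to a library total of 1000000, so genes below a few CPM carry large counting errors. No source says that the libraries came from separate cultures, so the p-values may measure technical spread only. The comparison asks which transcripts differ after 24 h of CTI-2, and the series title names metastasis, epithelial-mesenchymal transition and MAPK signalling as its interest.

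After CTI-2, the polyamine-degrading enzyme gene SAT1 rose 2.88-fold and IFRD1, a transcriptional co-regulator gene, rose 1.96-fold, while FASN, the fatty acid synthase gene, was 4.10-fold lower and TGFBI, a secreted matrix protein gene, was 2.21-fold lower. The calls of SAT1, IFRD1 and FASN held whichever library was left out, but that of TGFBI was lost without control 2 or control 3. As groups, cholesterol synthesis genes, genes of the ATF4 and unfolded protein response, and mitochondrially encoded genes were lower than the other genes, and p53 target genes were higher, in camera with a preset correlation. None of these 4 list calls held with an estimated correlation (adjusted p = 0.078, 0.078, 0.748 and 0.408 in that order). Lists of MAPK cascade, ERK output, mesenchymal and epithelial genes did not pass the test. In all, 791 of 9848 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 334 of them higher and 457 lower (57.8% lower). Changes were modest: 6 of the higher and 154 of the lower genes changed by more than 2-fold, and the median log2 fold change was 0.45 among higher and -0.84 among lower genes. The balance of directions rested partly on control 2 and was not kept in DESeq2: without control 2 there were 957 higher and 653 lower genes (40.6% lower of 1610), and with DESeq2 there were 271 higher and 233 lower genes (46.2% lower of 504), which gave 7163 genes an adjusted p. Leaving out any other library gave 66.67 to 71.75% lower. Limma-voom and edgeR with DESeq2's size factors, on the 9848 genes, gave 58.4% and 59.0% lower. Of the 791 called genes, 773 had CPM that did not overlap between the groups, and 28.8% of all tested genes did not overlap, where chance gives 10%.

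Expression level and transcript properties differed between the genes that rose and those that fell. Among genes under 4 on the log2 CPM scale 7 rose and 156 fell, and among genes of 6 to 8 the numbers were 186 and 81. The higher genes had a median annotated transcript length of 1570 bases and a GC content of 46.8%, against 2598 bases and 55.3% for the lower genes. Control 2 carried more reads of short transcripts than controls 1 and 3: in the quintile of genes with the shortest transcripts, values deviated from their mean over libraries by a median of 0.08 in control 2, -0.09 in control 1 and -0.18 in control 3 on the log2 scale, against 0.07 in each of the CTI-2 libraries. Control 2 also lay nearest to the CTI-2 libraries on the first principal component (-8.16, against -23.1 for each of the other controls and 13.7 to 25.1 for CTI-2), which held 43.4% of the variance. Its log2 CPM correlated at r = 0.9826 with those of control 1, at r = 0.9795 with those of control 3 and at r = 0.9746 to 0.9807 with those of the CTI-2 libraries, correlations across genes within these libraries.

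**Figure D1:**
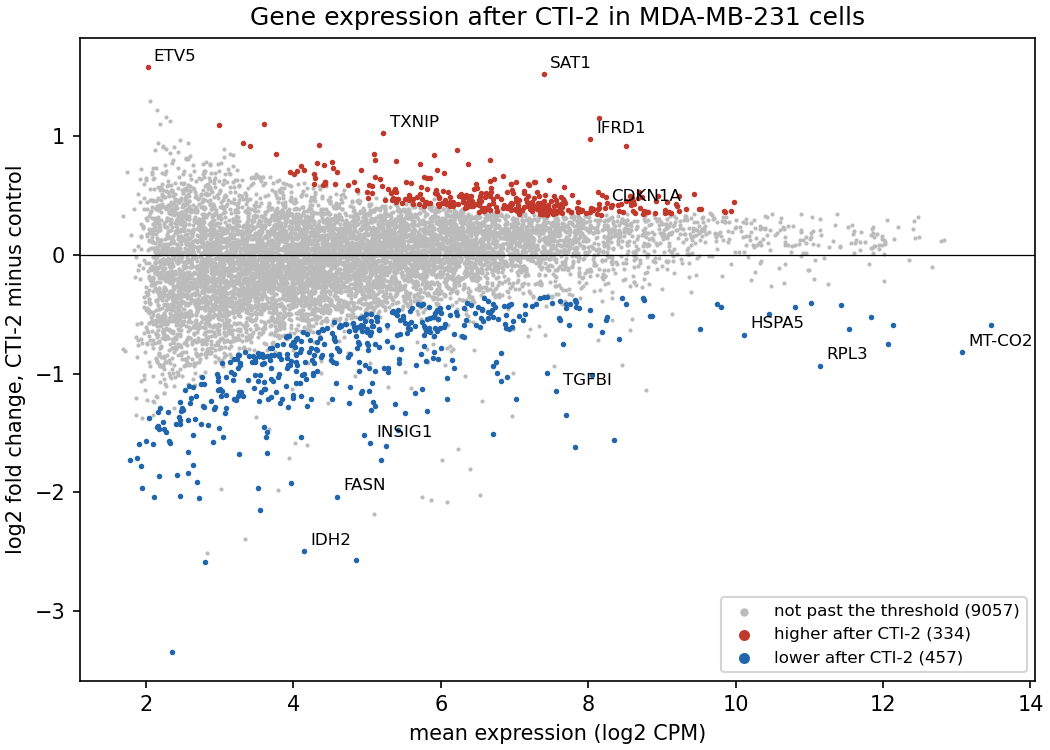
Mean expression (log2 CPM, horizontal) against the log2 fold change of CTI-2 minus control (vertical) for the 9848 tested genes. Red points are the 334 genes that were higher, blue points the 457 that were lower at an adjusted p under 0.05, and grey points did not pass; blue points extend further from 0 than red ones, most of all at low expression.

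Among the largest rises, SAT1 (chromosome X, 23783173 to 23786226, plus strand, in GENCODE 29 on GRCh38) went from 88.0 ± 6.53 CPM in controls to 244 ± 7.08 CPM after CTI-2 (SD, n = 3 per group; edgeR log2 fold change 1.53, SE 0.11, adjusted p = 4.6e-12). SAT1 encodes the rate-limiting enzyme of polyamine catabolism. IFRD1 rose from 179 ± 12.5 to 338 ± 15.5 CPM (log2 fold change 0.97, adjusted p = 1.7e-07). TXNIP, which encodes a thioredoxin-binding protein, rose from 24.5 ± 0.959 to 48.7 ± 6.14 CPM (1.03 on the log2 scale, adjusted p = 3.0e-05). The Notch target HES1 rose by 1.10, the stress gene GADD45A by 0.93 and the transcription factor gene IRF2 by 0.92 on the log2 scale. ETV5, described below with the ERK output genes, had the largest rise at 1.58. SDSL, KLRC3 and TMEM99 complete the 10 largest rises with log2 fold changes of 1.10, 0.94 and 0.89. TMEM99 overlaps KRT10 on the opposite strand, and whether the counting used strand is not given in the sources used here, so its value is uncertain. Leaving out a library ended the calls of ETV5, SDSL, KLRC3 and IRF2, with adjusted p up to 0.165, 0.133, 0.0825 and 0.0776 in that order, while SAT1, IFRD1, TXNIP, HES1, GADD45A and TMEM99 passed whichever library was left out. With all libraries IRF2 also missed the threshold in DESeq2 (adjusted p = 0.0788) and KLRC3 after thinning (adjusted p = 0.0603).

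Falls were larger than rises. FASN (chromosome 17, 82078333 to 82098332, minus strand, in GENCODE 29 on GRCh38) went from 37.7 ± 8.06 to 8.64 ± 2.79 CPM (SD, n = 3 per group; log2 fold change -2.04, SE 0.21, edgeR adjusted p = 7.5e-08). SCAND1 fell from 47.7 ± 11.4 to 8.12 ± 4.23 CPM (log2 fold change -2.57, adjusted p = 0.00028), and IDH2, the mitochondrial NADP-dependent isocitrate dehydrogenase gene, from 28.8 ± 14.3 to 4.67 ± 2.09 CPM (-2.49, adjusted p = 0.0061). TMEM175, the gene of a lysosomal potassium channel, had a log2 fold change of -2.58 on few reads, with 37, 25 and 30 counts in controls and 1, 10 and 3 counts in CTI-2 libraries. The interleukin-17 receptor subunit gene IL17RC (-2.15), PDLIM4 (-2.05), MACROD1 (-1.97), PRAF2 (-1.96), the zinc transporter gene SLC39A3 (-1.92) and C6orf120 (-1.91) made up the rest of the 10 largest falls. Control 1 had the highest CPM of all 6 libraries for each of these 10 genes. MACROD1 missed the threshold without CTI-2 library 2 (adjusted p = 0.056) and the other 9 passed whichever library was left out. SCAND1 overlaps CNBD2, which also fell (-0.93), and PRAF2, PDLIM4, MACROD1 and C6orf120 overlap other counted genes whose own log2 fold changes lay between -0.17 and 0.10, so their counts are uncertain.

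**Figure D2:**
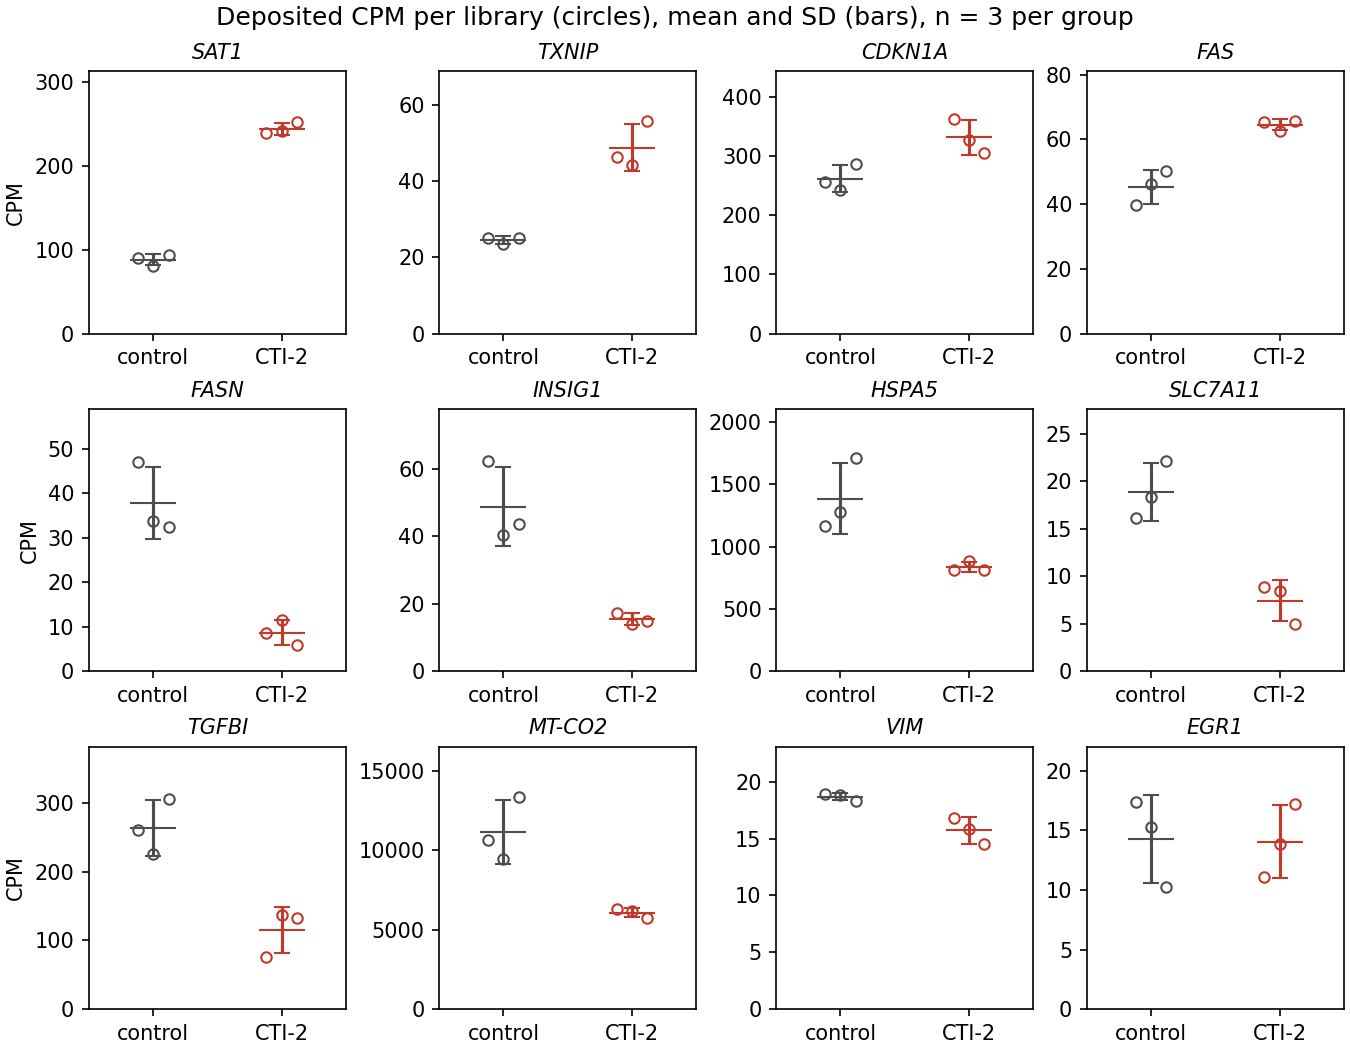
Deposited CPM of 12 named genes per library (circles) in the 3 control and 3 CTI-2 libraries, with the group mean (horizontal line) and SD (bars); each vertical axis starts at 0. SAT1 rose from a mean of 88.0 to 244 CPM and FASN fell from 37.7 to 8.64 CPM with no overlap, while EGR1 was at 14.3 and 14.0 CPM.

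Genes of the MAPK pathway, the signalling route from RAS to ERK and its stress-activated branches, showed no called change in their own transcripts. Of 26 listed MAPK cascade components 24 were tested and none passed; the list's median log2 fold change was -0.04 and its camera adjusted p was 0.837. MAPK3, which encodes ERK1, stood at 15.03 ± 2.18 CPM in controls and 13.1 ± 1.45 CPM after CTI-2 (adjusted p = 0.658), and the kinase gene RPS6KA1 had a log2 fold change of -0.12. At an unadjusted p under 0.05 the edgeR fit gave 2 of these genes, among them ARAF (0.33), and 2358 of all 9848 tested genes. DESeq2 and limma-voom gave 0 of the cascade genes at an adjusted p of 0.05. Of 18 listed ERK output genes only 6 had enough counts to be tested, and ETV5 alone was called (1.73 ± 0.343 CPM in controls, 4.97 ± 1.21 CPM after CTI-2, log2 fold change 1.58, SE 0.44, adjusted p = 0.019). ETV5 had 4 to 6 counts in the controls and 10 to 20 after CTI-2, and its call was lost without control 1 (adjusted p = 0.073) or CTI-2 library 1 (adjusted p = 0.165), in a range of 0.016 to 0.165 over the alternatives. When adjusted over the list alone 2 of the 6 tested genes were higher and 0 lower. The list as a whole had a camera adjusted p of 0.341. The ERK-induced genes EGR1 (14.3 ± 3.66 and 14.0 ± 3.06 CPM) and IER3, EPHA2 and DUSP4 (log2 fold changes of -0.15, 0.55 and 0.15) did not pass over all genes. DUSP6, with a count of at most 1 in any library, and FOSL1, with 1 to 8 counts per library, were below the filter. Of 15 tested AP-1 and immediate early genes only KLF10 passed (log2 fold change 0.50, adjusted p = 0.020). In this list 11 genes had a negative and 4 a positive log2 fold change (median -0.14, camera adjusted p = 0.742). KLF10 missed the threshold with library totals, DESeq2 or limma on log2 CPM and without control 3, CTI-2 library 2 or CTI-2 library 3 (adjusted p 0.0066 to 0.116 over the alternatives).

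Mesenchymal and epithelial gene lists did not move as groups. Of 19 tested mesenchymal genes 1 passed: TGFBI, which encodes a secreted matrix protein induced by TGF-beta, fell from 264 ± 40.7 to 115 ± 33.5 CPM (SD, n = 3 per group; log2 fold change -1.15, SE 0.19, edgeR adjusted p = 0.0066). DESeq2 called 2 mesenchymal genes, TGFBI and the collagen gene COL5A1 (log2 fold change -0.75, adjusted p = 0.213 in edgeR), and limma-voom also called 2. TGFBI lies on chromosome 5 at 136028895 to 136063818 on the plus strand in GENCODE 29 on GRCh38. Its call was lost without control 2 (log2 fold change -1.21, adjusted p = 0.071) or control 3 (-1.06, adjusted p = 0.102). The mesenchymal list had a median log2 fold change of -0.12 and a camera adjusted p of 0.837, with 2 genes lower when adjusted over the list alone. VIM (18.7 ± 0.320 and 15.7 ± 1.16 CPM), CDH2 (16.5 ± 3.48 and 13.8 ± 0.739 CPM), FN1 (5.03 ± 2.71 and 3.22 ± 0.937 CPM), SNAI1 (36.4 ± 1.05 and 33.1 ± 6.35 CPM) and ZEB1 (15.7 ± 1.45 and 17.1 ± 2.42 CPM) had adjusted p between 0.467 and 0.751. VIM is commonly described as abundant in MDA-MB-231, so its low level in all 6 libraries limits what these mesenchymal values say about the line, whose identity was not tested here. SNAI2 was at 1.39 ± 0.686 and 0.941 ± 0.908 CPM and was not tested. None of 12 tested epithelial genes passed over all genes, with 5 at an unadjusted p under 0.05, where 2358 of all 9848 tested genes lay. When adjusted over the list alone 1 was higher and 2 lower, while limma-voom gave 0 and DESeq2 gave MUC1 alone. The epithelial list had a median of 0.03, a mean of -0.07 and a camera adjusted p of 0.853. MUC1 came close (log2 fold change 0.35, adjusted p = 0.051). It overlaps another counted gene that rose (AL713999.1, 0.45, edgeR adjusted p = 0.00745), so its value is uncertain. KRT18 had 0.24 (adjusted p = 0.149), and CDH1, the E-cadherin gene, had 1 count in a CTI-2 library and 0 in the other 5 libraries. For a control library a count of 0 allows up to 0.763 to 1.28 CPM, so CDH1 was not detectable at this depth. Among matrix remodelling and invasion genes 1 of 19 tested members passed, the urokinase receptor gene PLAUR, which rose from 155 ± 25.1 to 212 ± 17.8 CPM (log2 fold change 0.50, adjusted p = 0.0065; camera adjusted p of the list 0.837). PLAUR missed the threshold without control 1 or CTI-2 library 3 (adjusted p up to 0.0868). MMP9 had 0 to 3 counts per library and was not tested. Of 10 tested TGF-beta and YAP targets TGFBI was again the only call, and the list had a median of 0.27 and a camera adjusted p of 0.415.

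Sterol synthesis genes included 5 that fell. Of 20 tested cholesterol synthesis genes 5 were lower, 15 did not pass and none were higher over all genes, 13 were lower when adjusted over the list alone, and 19 had a negative log2 fold change (median -0.39, camera adjusted p = 1.4e-05). With an estimated correlation the list's adjusted p was 0.078. INSIG1 (chromosome 7, 155297776 to 155310235, plus strand, in GENCODE 29 on GRCh38), whose product retains the sterol sensor in the endoplasmic reticulum, fell from 48.9 ± 11.8 to 15.5 ± 1.72 CPM (SD, n = 3 per group; log2 fold change -1.59, SE 0.18, edgeR adjusted p = 2.1e-07). The isopentenyl diphosphate isomerase gene IDI1 fell from 74.5 ± 10.9 to 48.8 ± 4.84 CPM and DHCR7, the gene of the last enzyme on the way to cholesterol, from 244 ± 40.1 to 172 ± 4.78 CPM. The lanosterol synthase gene LSS also passed, with a log2 fold change of -0.47, but LSS was not among the 4 members that DESeq2 called. INSIG1 passed whichever library was left out, IDI1 missed without CTI-2 library 3 (adjusted p = 0.0624) and DHCR7 without CTI-2 library 1 or 2 (adjusted p up to 0.0685).

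The ATF4 and unfolded protein response list, which joins amino acid stress genes with endoplasmic reticulum chaperones, was also lower. Of 22 tested members 7 were lower and 1 higher, against 14 and 1 when adjusted over the list alone, and 20 had a negative log2 fold change (median -0.41, camera adjusted p = 1.3e-05). With an estimated correlation its adjusted p was 0.078. The chaperone gene HSPA5 (chromosome 9, 125234853 to 125241330, minus strand, in GENCODE 29 on GRCh38) fell from 1385 ± 284 to 837 ± 42.5 CPM (SD, n = 3 per group; log2 fold change -0.67, SE 0.12, edgeR adjusted p = 0.0006). The cystine transporter gene SLC7A11 fell from 18.9 ± 3.01 to 7.43 ± 2.13 CPM (-1.25, adjusted p = 0.00093), and PHGDH, which opens serine synthesis, from 363 ± 11.3 to 240 ± 8.60 CPM (-0.55, adjusted p = 0.0011). PDIA4, CALR, ASNS and TRIB3 were the other lower members, with log2 fold changes of -0.41, -0.38, -0.55 and -0.46. DDIT3, the CHOP transcription factor gene of the same response, moved against the list and rose by 0.47. DESeq2 called 5 members of the list, HSPA5, SLC7A11, PHGDH and PDIA4 among them, and did not call DDIT3, CALR, ASNS or TRIB3. HSPA5, SLC7A11 and PHGDH passed whichever library was left out.

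Mitochondrially encoded transcripts were lower after CTI-2, and their share of all counts was 4.98% ± 1.02 in controls and 3.16% ± 0.166 after CTI-2 (SD, n = 3 per group; two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). The share was 4.70, 4.13 and 6.12% in controls 1 to 3 and 3.27, 3.24 and 2.97% in CTI-2 libraries 1 to 3, each with a 95% exact binomial interval within 0.05 percentage points of it. Of the 13 genes 9 fell, with a list median of -0.59 and a camera adjusted p of 2.5e-05, which became an adjusted p of 0.748 with an estimated correlation. MT-CO2, a cytochrome c oxidase subunit gene, fell from 11160 ± 2000 to 6071 ± 295 CPM (log2 fold change -0.82, SE 0.13, edgeR adjusted p = 0.00012), MT-CO3 from 5485 ± 1290 to 3127 ± 233 CPM and MT-ATP8 from 360 ± 72.3 to 221 ± 12.1 CPM. MT-ND5 and MT-ND6 did not pass and had log2 fold changes of 0.07 and -0.05. With each library's trend with transcript length removed, 1 of the 9 calls was left, although the list's median log2 fold change went from -0.59 to -0.67, as the median SE rose from 0.13 to 0.19. MT-CO2 then had a log2 fold change of -0.9985 (adjusted p = 0.0518) and MT-CO3 of -0.92 (adjusted p = 0.1001). Nuclear oxidative phosphorylation genes went both ways, and 1 of 24 tested members passed, ATP5PO, which rose by 0.36 on the log2 scale (adjusted p = 0.040), and the list had a median of 0.15, a mean of -0.07 and a camera adjusted p of 0.261. UQCRFS1 and COX5A had the lowest values of this list, with log2 fold changes of -2.18 and -1.80 and no overlap between the groups, and missed the threshold in edgeR (adjusted p = 0.158 and 0.0862). DESeq2 called 4 of the nuclear genes, UQCRFS1, COX5A, ATP5PO and COX6C (edgeR log2 fold change 0.36). ATP5PO kept its call only without control 2 among the libraries left out. Of 28 tested ribosomal protein genes 1 passed, RPL3, which fell from 2999 ± 194 to 1522 ± 83.0 CPM (log2 fold change -0.93, adjusted p = 3.5e-06), while 22 of the 28 had a positive value and the list's median was 0.08 (camera adjusted p = 0.341). The ribosomal protein list made up 7.12% ± 0.605 of counts in controls and 7.22% ± 0.0998 after CTI-2 (exact permutation p = 0.7). Without control 2 the ribosomal protein and nuclear oxidative phosphorylation lists passed as higher, with camera adjusted p of 0.0017 and 0.019. With all libraries and an estimated correlation, the camera adjusted p of both lists was 0.8705.

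**Figure D3:**
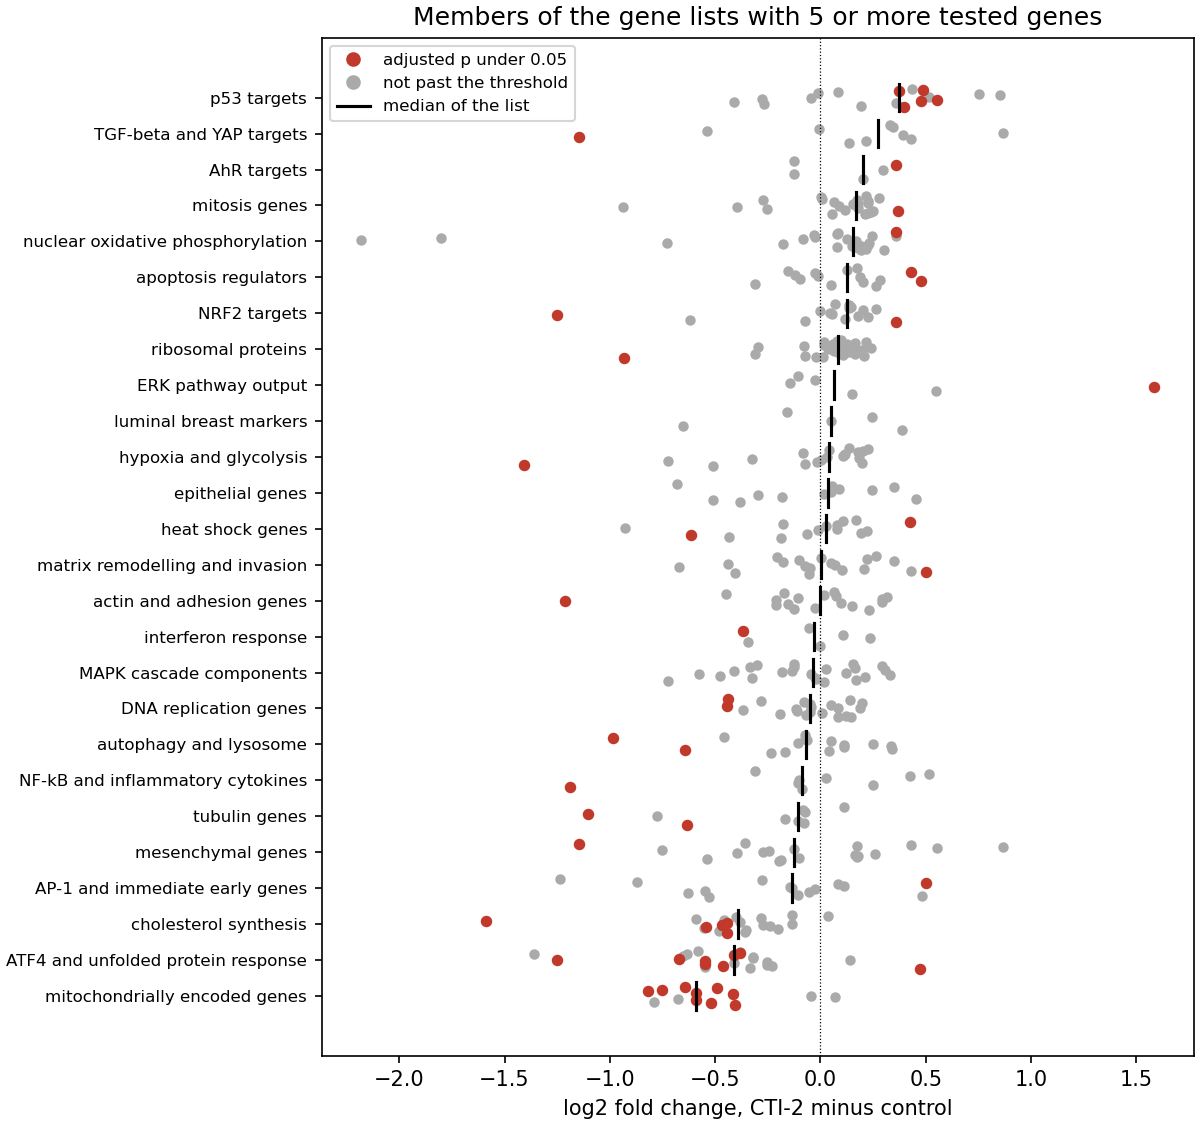
Log2 fold change (CTI-2 minus control) of each tested member of the 26 gene lists with 5 or more tested genes; red points passed an adjusted p of 0.05 over all genes, grey points did not, and black bars mark list medians. Mitochondrially encoded, ATF4 and unfolded protein response and cholesterol synthesis genes have medians of -0.59, -0.41 and -0.39, and p53 targets have 0.37.

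Among targets of p53, 5 genes rose. Of 17 tested members 5 passed and all 5 were higher, while 9 were higher and 1 lower when adjusted over the list alone (median log2 fold change 0.37, camera adjusted p = 0.0025). In camera with an estimated correlation the list's adjusted p was 0.408. With fry, which tests the list against no change rather than against the other genes, the adjusted p was 0.0777. The death receptor gene FAS rose from 45.3 ± 5.31 to 64.6 ± 1.63 CPM (SD, n = 3 per group; log2 fold change 0.56, edgeR adjusted p = 0.0074), the glycolysis regulator gene TIGAR from 65.6 ± 4.86 to 88.9 ± 6.38 CPM (0.48, adjusted p = 0.010) and CDKN1A, the gene of the cell cycle inhibitor p21, from 262 ± 23.0 to 332 ± 29.4 CPM (0.40, adjusted p = 0.018). FAS missed without control 1 (adjusted p = 0.061), TIGAR without CTI-2 library 2 (adjusted p = 0.085), and CDKN1A without control 1, CTI-2 library 1 or CTI-2 library 2 (adjusted p up to 0.160). Among 15 tested apoptosis regulators CASP9 and BAX rose, by 0.43 and 0.48, and the list had a camera adjusted p of 0.261; BAX lost its call in 8 of 13 alternatives that kept all libraries, and CASP9 in 4 of 13, DESeq2 and library totals among them, and in 4 of 6 fits that left out a library (adjusted p up to 0.181). Of 24 tested mitosis genes AURKA alone passed (0.37, adjusted p = 0.046), although 20 had a positive value (median 0.17, camera adjusted p = 0.110). Without control 3 the mitosis list passed with a camera adjusted p of 0.043. With all libraries and an estimated correlation, its camera adjusted p was 0.408. Of 21 tested DNA replication genes CHAF1A and RRM2 fell, both by 0.44 on the log2 scale, and the list had a camera adjusted p of 0.837. RRM2 overlaps another counted gene that also fell (AC007240.1, -0.90), so its value is uncertain. AURKA, CHAF1A and RRM2 each missed the threshold with DESeq2 and without some of the libraries.

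Other stress and signalling lists showed isolated calls. Of 15 heat shock genes HSPA8 fell (-0.61, adjusted p = 0.0029) and CHORDC1 rose (0.42, adjusted p = 0.016), with a list median of 0.02 and a camera adjusted p of 0.902. CHORDC1 missed the threshold without control 1, CTI-2 library 1 or CTI-2 library 3 (adjusted p up to 0.0947). Of 16 tested NRF2 targets SLC7A11 fell and the quinone reductase gene NQO1 rose (0.36, adjusted p = 0.043; list median 0.13, camera adjusted p = 0.495), and NQO1 was also the only call among 5 tested AhR targets (camera adjusted p = 0.471). NQO1 kept its call only without control 2 among the libraries left out. CXCL8, the interleukin-8 gene, fell from 12.6 ± 2.29 to 5.42 ± 0.655 CPM (-1.19, adjusted p = 0.0051) as the only call among 9 tested NF-kB and cytokine genes (camera adjusted p = 0.853). The interferon-induced gene BST2 fell by 0.37 on the log2 scale (adjusted p = 0.042) as the only call among 6 tested interferon response genes (camera adjusted p = 0.837), and its call was lost in 5 of 6 fits that left out a library. ANKRD37 was the only call among 19 tested hypoxia and glycolysis genes (-1.41, adjusted p = 0.044; camera adjusted p = 0.837), on 2 to 28 counts per library. Its call was lost with library totals, limma-voom and limma on log2 CPM, and without control 1, CTI-2 library 1 or CTI-2 library 2 (adjusted p up to 0.266). Too few metallothionein genes were tested for a list test, but 2 of 3 passed: MT2A rose from 575 ± 42.3 to 797 ± 18.8 CPM and MT1E from 70.0 ± 11.3 to 101 ± 0.276 CPM (log2 fold changes 0.52 and 0.56, adjusted p = 0.0038 and 0.0055).

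Cytoskeletal and autophagy genes gave single falls without a list call. FLNA, the gene of the actin cross-linker filamin A, fell from 184 ± 40.3 to 75.7 ± 19.7 CPM (SD, n = 3 per group; log2 fold change -1.21, edgeR adjusted p = 0.0013) as the only call among 18 tested actin and adhesion genes, whose camera adjusted p was 0.956; without control 3 FLNA had an adjusted p of 0.060. Of 9 tested tubulin genes TUBB3 and TUBA1A fell (-1.11 and -0.63, adjusted p = 0.048 and 0.047) and 8 had a negative value (camera adjusted p = 0.239). Both calls were lost in most fits that left out a library, and tubulin genes share sequence with near-identical copies, so TUBA1A is uncertain. Of 16 tested autophagy and lysosome genes 2 were lower, among them the kinase gene ULK1, which fell from 32.9 ± 7.53 to 19.7 ± 3.35 CPM (-0.64, adjusted p = 0.023), with a camera adjusted p of 0.837 for the list. ULK1 missed the threshold with DESeq2, with the GC trend removed and without control 1, control 3 or CTI-2 library 3 (adjusted p up to 0.121). The median, the mean and the camera direction differed in sign for the epithelial, heat shock, NRF2, hypoxia and glycolysis, actin and adhesion, nuclear oxidative phosphorylation and luminal lists, none of which passed.

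Markers of other cell types did not differ by the test. Of 14 luminal breast markers 5 were tested and none passed in edgeR, limma-voom or DESeq2, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.837), and KRT8 stood at 83.5 ± 2.13 and 83.9 ± 4.68 CPM. Over all 9848 tested genes 2358 had an unadjusted p under 0.05 in edgeR. Among blood and immune markers CSF1R alone had enough counts, at 4.94 ± 0.552 CPM in controls and 4.69 ± 0.878 CPM after CTI-2. Of 12 fibroblast and endothelial markers 3 were tested and none passed in edgeR, limma-voom or DESeq2, with 1 at an unadjusted p under 0.05; COL1A1 was at 73.9 ± 19.0 and 59.2 ± 1.08 CPM and PDGFRB at 19.96 ± 4.78 and 13.6 ± 1.30 CPM (SD, n = 3 per group). Genes without a symbol, listed under identifiers of the authors' own, took 7 of the rises and 50 of the falls; ONT.10344 rose by 1.16 and ONT.10541 fell by 3.34 on the log2 scale.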

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

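All 55 called genes named by the rule kept their sign under each setting that gave them a value, 38 kept an adjusted p under 0.05 in each such setting with all libraries (the stricter p and fold change aside), and 26 also whichever library was left out; some, such as ETV5 (10 of 13 settings), were not tested under the stricter filter or after thinning, or given an adjusted p by DESeq2. The 791 calls stood against 504 with DESeq2 (233 lower). The stricter tests gave 306 at an adjusted p of 0.01 (107 higher, 199 lower) and 23 for a fold change over 1.5 (2 higher, 21 lower). DESeq2 gave 7163 genes an adjusted p, among them 697 of the 791, and called 448 of those 697. Fewer genes with an adjusted p therefore do not alone account for its fewer calls. Leaving out a library gave 400 to 1610 calls, 113 to 957 higher and 287 to 653 lower, lowest without CTI-2 library 3 and highest without control 2, and the cause was not tested. Other normalizations, filters and limma gave 682 to 882 calls and the same sign for each call they tested. The replicate number as a block gave 942 calls. Deviations of same-numbered libraries correlated at -0.05, 0.01 and -0.12, and those of differently numbered libraries at -0.10 to 0.14. With 3 libraries per group this cannot show whether the numbers pair the libraries. Of 26 lists 4 passed. In camera with an estimated correlation, which widens the null where members vary together, 0 passed (2 had an unadjusted p under 0.05). With fry, which tests a list against no change rather than against the other genes, 2 passed. In camera with the preset correlation 6 passed without control 2, and 6 without the low-count filter, which let more lists be tested. Without control 3, or with the length trend removed, 5 passed. Lists under DESeq2 and glmTreat, and lists after thinning, were not run. The difference in mitochondrially encoded share was -1.25 to -2.25 percentage points over the libraries left out. The adjusted p of the ERK output, MAPK cascade, mesenchymal and epithelial lists stayed at 0.1 or above wherever they were tested, and the ERK output list was not tested under the filter of 20 counts. With each library's length trend removed, chosen after seeing the data, the mitosis list passed (adjusted p = 0.026; 0.036 without the low-count filter). Low or absent counts limit the ERK output list, 12 of whose 18 genes were not tested.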

Other observations

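The added lists, the genes named in these first paragraphs, the removal of length and GC trends and the thinning were chosen after the data were seen. The adjusted p of the added lists do not account for that choice and are descriptive only. Of 16 fatty acid synthesis genes 5 fell and none rose, FASN, ACSL3, SCD, PNPLA3 and SREBF1, with a median log2 fold change of -0.19 (camera adjusted p = 0.0016 over 7 added lists, and an adjusted p of 0.275 with an estimated correlation). ACSL3 fell from 138 ± 15.2 to 69.6 ± 5.27 CPM and SCD, the stearoyl-CoA desaturase gene, from 68.4 ± 10.9 to 38.6 ± 3.09 CPM (SD, n = 3 per group; edgeR adjusted p = 2.5e-06 and 0.00057). PLIN2, the lipid droplet coat gene, moved the other way, from 74.7 ± 2.38 to 126 ± 4.91 CPM (log2 fold change 0.80, adjusted p = 2.0e-05). Of 11 tested protein disulfide isomerase genes and relatives 4 fell and 1 rose (camera adjusted p = 0.098), the steepest being PDIA3, from 493 ± 139 to 161 ± 9.84 CPM (log2 fold change -1.56, adjusted p = 1.3e-05). Among 10 tested polyamine genes SAT1 and ODC1, the enzyme genes that open breakdown and synthesis, both rose, ODC1 from 99.2 ± 16.5 to 145 ± 5.55 CPM (adjusted p = 0.0012; list adjusted p = 0.033, with an adjusted p of 0.456 with an estimated correlation and of 0.135 with the length trend removed). Of 20 ribosome biogenesis genes 4 rose, among them UTP4 (89.9 ± 10.5 to 138 ± 6.84 CPM), and the list had an adjusted p of 0.021, or an adjusted p of 0.275 with an estimated correlation. Proteasome, vacuolar ATPase and aminoacyl-tRNA synthetase lists did not pass (camera adjusted p = 0.059, 0.059 and 0.541). In the vacuolar ATPase list 12 of 15 members had a positive value (median 0.15), ATP6V1G1 rose and ATP6AP1 fell, the latter from 153 ± 12.8 to 71.2 ± 16.0 CPM.

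Levels of some genes in all 6 libraries leave the identity of the line in doubt, and it rests here on the labels alone. CDKN2A, which is commonly described as deleted in MDA-MB-231, was at 612, 442 and 337 CPM in controls 1 to 3 and 321, 293 and 255 CPM in CTI-2 libraries 1 to 3 (log2 fold change -0.63, adjusted p = 0.090). VIM, commonly abundant in this line, was at 14.5 to 18.9 CPM, while S100A4 was at 2251 to 2802 CPM and KRT17 at 1311 to 1645 CPM. GAPDH was at 60.5 to 76.8 CPM beside its glycolytic neighbours PKM at 4064 to 4965 CPM and PGK1 at 1550 to 1718 CPM, and the gene name table used here holds 65 genes named as GAPDH pseudogenes against 5 for PKM and 2 for PGK1. FTH1 was at 70.6 to 102 CPM with 25 named pseudogenes, FTL at 1807 to 2153 CPM with 16, and TUBA1B at 1.01 to 2.55 CPM with 0. HSPA8, with 17 named pseudogenes, was at 42.1 to 82.6 CPM, so its fall rests on the reads that the counting kept. The name table holds 0 genes named as pseudogenes of VIM or CDKN2A. Whether these levels come from the counting or from the cells was not tested.

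Among genes with an annotated transcript 407 were lower and 328 higher. Removing each library's trend with transcript length left 402 lower calls, 335 of them among the 407, and removing the trend with GC content left 375, 342 of them shared, which argues against either trend as the whole source of the lower calls. Thinning every library to the smallest total left 59.5% of calls lower, which argues against unequal depth. The excess of lower over higher calls was lost without control 2 (40.6% lower) and with DESeq2 (46.2% lower), so it is open whether CTI-2 lowers more transcripts than it raises. Without control 2 the lower calls also rose, to 653, but the higher calls rose further, to 957. Leaving out any other library gave 66.67 to 71.75% lower. With 10 splits of the 6 libraries no share under 0.05 can be had: the real split was the 1 split with as many calls (791, 334 higher and 457 lower), the highest of the others was 0, and for lists 2 splits reached 4, the highest other being 4. Most of the other splits called at least 1 list.

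Mitochondrially encoded transcripts had a median log2 fold change of -0.59, which became -0.67 with the length trend removed and -0.62 with the GC trend removed, against either trend as the cause. The length correction left 1 of the 9 calls, because the median SE rose from 0.13 to 0.19 while the median fold change did not shrink. The median of 291 solute carrier and TMEM genes lay 0.02 below expression-matched genes (difference -0.0249, 95% bootstrap interval -0.077 to 0.015). Against 457 falls and 334 rises among all 9848 tested genes, 24 of these genes fell and 6 rose. Their transcripts are nuclear and were chosen as translated at the endoplasmic reticulum. They therefore cannot show whether RNA held inside mitochondria was lost, and such a loss stays open. That CTI-2 lowers mitochondrial transcripts in these cells may be kept as a hypothesis, found and tested on the same data. RNA quality and cell handling, which can also shift this share, were not measured and stay open.

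The 42 tested cholesterol synthesis and unfolded protein response genes had a median log2 fold change of -0.41, and -0.38 and -0.39 with the length or the GC trend removed, so neither trend accounts for it. The 291 solute carrier and TMEM genes showed no such fall as a set (the same difference of -0.0249), but 24 fell and 6 rose. Of all 9848 tested genes 457 fell and 334 rose. Solute carrier and TMEM genes do not stand for every transcript translated at the endoplasmic reticulum. They therefore cannot decide whether a general loss of such transcripts occurred. That CTI-2 lowers cholesterol synthesis and unfolded protein response genes may be kept as a hypothesis, found and tested on the same data. Whether both lists respond together was not tested. Medium, lipid supply and cell density in the cultures were not measured and stay open.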
